A study of Mus musculus with 12 samples.

How the data were processed

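The series holds 12 arrays of primary mixed glial cells from wild-type and IL-1R1-deficient mice, given 10 ng/ml rrIL-1β or vehicle for 4 hours (1 sample's label writes IL-1β for the same treatment). Per the labels, total RNA was extracted with TRIzol, treated with DNase and reverse transcribed with a radio-labelled nucleotide. The deposited values are linear spot intensities, positive decimals whose scale differs between cultures. The software, background correction, normalization and filter that the authors used to make these intensities are not given in the sources used here. From the values themselves, the 2 arrays of a culture lack the same probes, 370 to 2011 of 8734, and their medians differ by at most 0.07 on the log2 scale. How this came about is not given in the sources used here. The lowest intensity of an array was 0.225 to 0.368 of its median, which leaves open how much background the values still hold, and fold changes are given as the intensities show them.

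Gene names came from the platform annotation. Of 8734 probes 7153 had 1 gene symbol, 387 had several and 1194 had none. Among the tested probes 4665 had 1 symbol, from 3997 genes. A current table of mouse gene names (GRCm38.p6) changed 0 of the symbols. No coordinates of the probes were used.

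Before the data were examined, the following were set: the groups, the comparisons, the tests, 25 gene lists, the rule for named genes and a first set of alternatives. Values were quantile-normalized between arrays on the log2 scale with limma 3.58.1 (R 4.3.3), because array medians differed by more than 0.1. Each probe was fitted with lmFit and eBayes, with culture as a block and 1 IL-1β term per genotype, and the contrast of these terms tested the difference between genotypes. The genotype difference in vehicle glia came from 4 group means with culture as a random block through duplicateCorrelation (statmod 1.5.0), at a correlation within cultures of 0.388. P-values were adjusted by Benjamini and Hochberg over all tested probes, with a threshold of 0.05, and are two-sided. Errors are standard errors of the fit (SE) or standard deviations between arrays (SD).

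The pairing came from the design text, which states paired treatments, and from the replicate numbers in the labels. The deviations of the 2 arrays of a culture from their group means were correlated across probes. This r was 0.562 for the IL-1R1-deficient cultures and 0.468, 0.582 and 0.261 for the wild-type cultures. With 2 IL-1R1-deficient cultures the deviations mirror each other, so 0.562 is 1 value. Arrays scaled or filtered together could correlate too, so these values cannot tell pairing by culture from joint processing. Like-numbered cultures of the genotypes were not treated as pairs, and their mean deviations correlated at 0.271 and 0.082.

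The following were chosen after seeing the data. The pair of IL-1R1-deficient replicate 3 was left out because its columns were rescaled copies of 2 others, so all fits rest on 10 arrays, and the planned fit on 12 columns (4698 complete probes) stands beside them. Fold changes in wild-type glia varied with the order of the probes, with a period of 24 and of 384 probes, as in plates of 16 by 24 wells, and with a step after plate 11 of 23; this layout was inferred from the values, and no spot coordinates were used. A second version of every comparison therefore had this position trend removed: in each of the 2 parts, the deviation of an array from the mean of all arrays was smoothed over plate row and column (loess, span 0.2) and subtracted. The correlation within cultures was then 0.452. Probes missing on any of the 10 arrays were left out, which kept 5713 (65.4%).

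The method was tested on simulated data with the same layout and 50 changed probes at each size. Without a position trend the planned fit recovered 40% of changes of 0.5, 94% of changes of 1 and 100% of larger ones on the log2 scale, with 8 false calls among 175. With an added trend, the same in every wild-type IL-1β array, the planned fit made 1611 false calls among 1784. The data themselves gave 353 calls. After trend removal the simulated data gave 18 false calls among 168, with 82% of changes of 1 recovered.

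Gene lists were tested with camera at a preset correlation of 0.01, with 1 probe per gene (the brightest), for the 23 lists with 5 or more measured genes, adjusted over these lists. Each was repeated with an estimated correlation and with fry. For the genotype difference the list tests used the 4 group means without a culture block, so the arrays of a culture counted as independent. In each comparison the rule named up to 12 genes per direction with the smallest p among those past the threshold and changed alike in every pair. For the difference between genotypes it required instead that the fold changes of the genotypes did not overlap. For the vehicle glia it required this of the intensities. Where fewer passed, up to 5 per direction were filled in by the smallest p, and these are said not to pass. It also named a fixed set of inflammatory genes, of which the tested probes held Il1r1, Nfkbia and Lcn2, the others being not analysed here, and up to 4 members per list. Other probes of a named gene are reported where they differ.

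Other settings covered the pairing, the normalization, filters on dim probes, an offset of 5037 (the 10th percentile of the values) before taking logarithms, the variance model and each culture left out in turn. Added after seeing the data were the part medians alone, a normexp background correction (offset 50), probes with gaps, and the copied columns left out together with their sources. Also added were median centring with a brightness trend removed, and the planned settings with the position trend removed. Python 3.11.15 and matplotlib 3.10.9 drew the figures.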

Results

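Gene expression was measured in primary mixed glial cells of wild-type mice and of mice that lack IL-1R1, the signalling receptor for interleukin-1. The cells had been kept for 10 to 12 days after isolation and received 10 ng/ml rrIL-1β, the name used in the labels, or vehicle for 4 hours. Radio-labelled cDNA was hybridised to 12 arrays, 3 replicates in each of 4 groups, and the labels pair the treatments within independent biological replicates of each genotype. The median deposited intensity per array lay between 4649 and 60399, and the number of arrays limits the precision of every value.

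The 12 deposited columns held 10 distinct arrays. The column of IL-1R1-deficient IL-1β replicate 3 equalled that of IL-1R1-deficient vehicle replicate 1 divided by 1.67 at 6531 of 6584 shared probes (within 1e-04 on the log2 scale). The column of IL-1R1-deficient vehicle replicate 3 equalled that of wild-type vehicle replicate 1 at 1 ratio, 1.12, at 5959 of 5982 shared probes. Across all other pairs of columns at most 0.0857% of probes shared 1 ratio. The comparisons therefore used 3 wild-type pairs and 2 IL-1R1-deficient pairs, and 5713 of 8734 probes had a value on all 10 arrays.

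**Figure D1:**
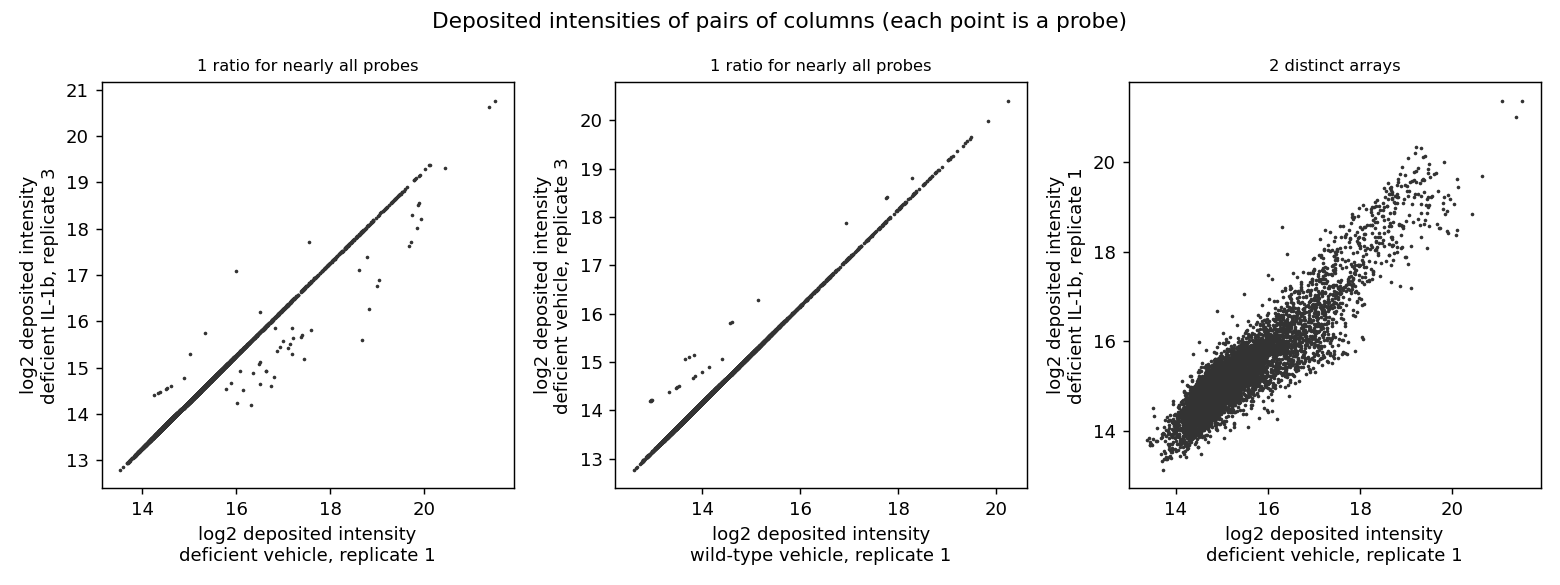
Each point is 1 probe, with the log2 deposited intensity of 1 column on each axis. In the left and middle panels, which hold the columns of IL-1R1-deficient replicate 3, 99.2% and 99.6% of probes lie on 1 line, while the right panel shows the scatter between 2 distinct arrays of 1 culture.

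The Il1r1 probe did not separate the genotypes. Its mean log2 intensity after normalization was 13.96 ± 0.14 (SD, n = 2) in IL-1R1-deficient vehicle glia and 13.87 ± 0.18 (SD, n = 3) in wild-type vehicle glia. With IL-1β it was 14.06 ± 0.15 (SD, n = 2) and 14.44 ± 0.52 (SD, n = 3). Single arrays lay between 13.73 and 15.03, at the 9.6 to 79.5 percentile of all probes. The sources used here do not give the deleted part of the gene or the place of the probe in it, so these values check nothing about the genotype labels.

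IL-1β raised Ptx3, Lcn2 and Ccl12 in wild-type glia, the comparison that asks which genes respond to the cytokine when its receptor is present. Ptx3, a long pentraxin that binds microbes and complement, rose 8.95-fold (log2 3.16 ± 0.34 SE, n = 3 pairs), or by log2 2.39 without wild-type replicate 1. Lcn2, which sequesters iron-loaded siderophores, rose 7.44-fold (SE 0.21 on the log2 scale), and Ccl12, a chemokine that attracts monocytes, rose 5.71-fold (SE 0.245). Steap4, a metalloreductase, rose 4.95-fold, Nfkbia, the inhibitor that holds NF-κB in the cytoplasm, rose 3.46-fold, and Tnfaip2, a transcript induced by tumour necrosis factor, rose 2.57-fold. Id4, an inhibitor of basic helix-loop-helix factors, was 3.03-fold lower (log2 -1.60 ± 0.19 SE), and Slc38a1, a glutamine transporter, was 2.04-fold lower (log2 -1.03 ± 0.18 SE). The size depended on the processing. Across other settings the log2 changes ran from 2.4 to 3.9 for Ptx3, 2.6 to 4.1 for Lcn2 and 2.1 to 3.5 for Ccl12. They ran from 2.0 to 3.5 for Steap4, 1.6 to 2.4 for Nfkbia and 1.2 to 2.0 for Tnfaip2. For Id4 they ran from -3.0 to -1.3, and for Slc38a1 from -1.3 to -0.8.

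All 8 of these genes moved the same way in 3 of 3 pairs, which the rule for naming them required. In limma their adjusted p lay between 1.09e-05 for Lcn2 and 0.00968 for Slc38a1. A second probe gave log2 changes of 2.26 for Ccl12 and 1.57 for Nfkbia. Fold changes in wild-type glia also followed the place of a probe in a layout inferred from the probe order, and values with that trend removed are given beside the others. After removal the log2 changes were 3.53 for Ptx3, 3.22 for Lcn2, 2.57 for Ccl12, 2.05 for Steap4, 1.62 for Nfkbia, 1.24 for Tnfaip2, -1.28 for Id4 and -0.80 for Slc38a1. All 8 still passed, Slc38a1 with the highest adjusted p, 0.0233, which was lost in 12 of 19 other settings. The interferon-inducible GTPases Gbp3 and Gbp7 and the oncostatin M receptor Osmr rose 3.07-fold, 2.78-fold and 2.61-fold, with log2 changes of 1.13, 0.88 and 0.82 after trend removal (adjusted p = 0.00512, 0.0138 and 0.0495, the last lost in 14 of 20 other settings). A second probe of Gbp7 gave 0.62 before and 0.73 after trend removal (adjusted p = 0.05 and 0.0685). Whether related transcripts, such as those of the Gbp family or of Ccl12 and Ccl2, hybridised to each other's probes was not tested.

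The other named genes passed in the quantile-normalized values and no longer passed with the position trend removed. Mir17hg, the host transcript of a microRNA cluster, changed from log2 1.25 ± 0.17 to 0.77 ± 0.17 (SE, adjusted p = 0.0921), Rrad, a small GTPase, from 1.10 to 0.55 (0.107) and Zcchc10 from 1.24 to 0.61 (0.146). Scpep1, Hey1, Maged1, Cops4, Fhl1, Trim35, Cst3, Cul7, Kmt2e and Rfc1 had log2 changes between -1.32 and -0.84, which became -0.95 to -0.40 (adjusted p between 0.0662 and 0.265). Second probes gave -0.06 for Hey1, -0.32 for Maged1, 0.09 for Trim35, and 0.03 and 0.58 for Kmt2e. After trend removal first and second probes had -0.91 and -0.46 for Hey1, -0.80 and -0.07 for Maged1, -0.63 and -0.57 for Trim35, and -0.40 against 0.04 and 0.12 for Kmt2e. Il1r1 itself had a log2 change of 0.58 ± 0.18 (SE, adjusted p = 0.0794), and 0.29 with the trend removed.

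**Figure D2:**
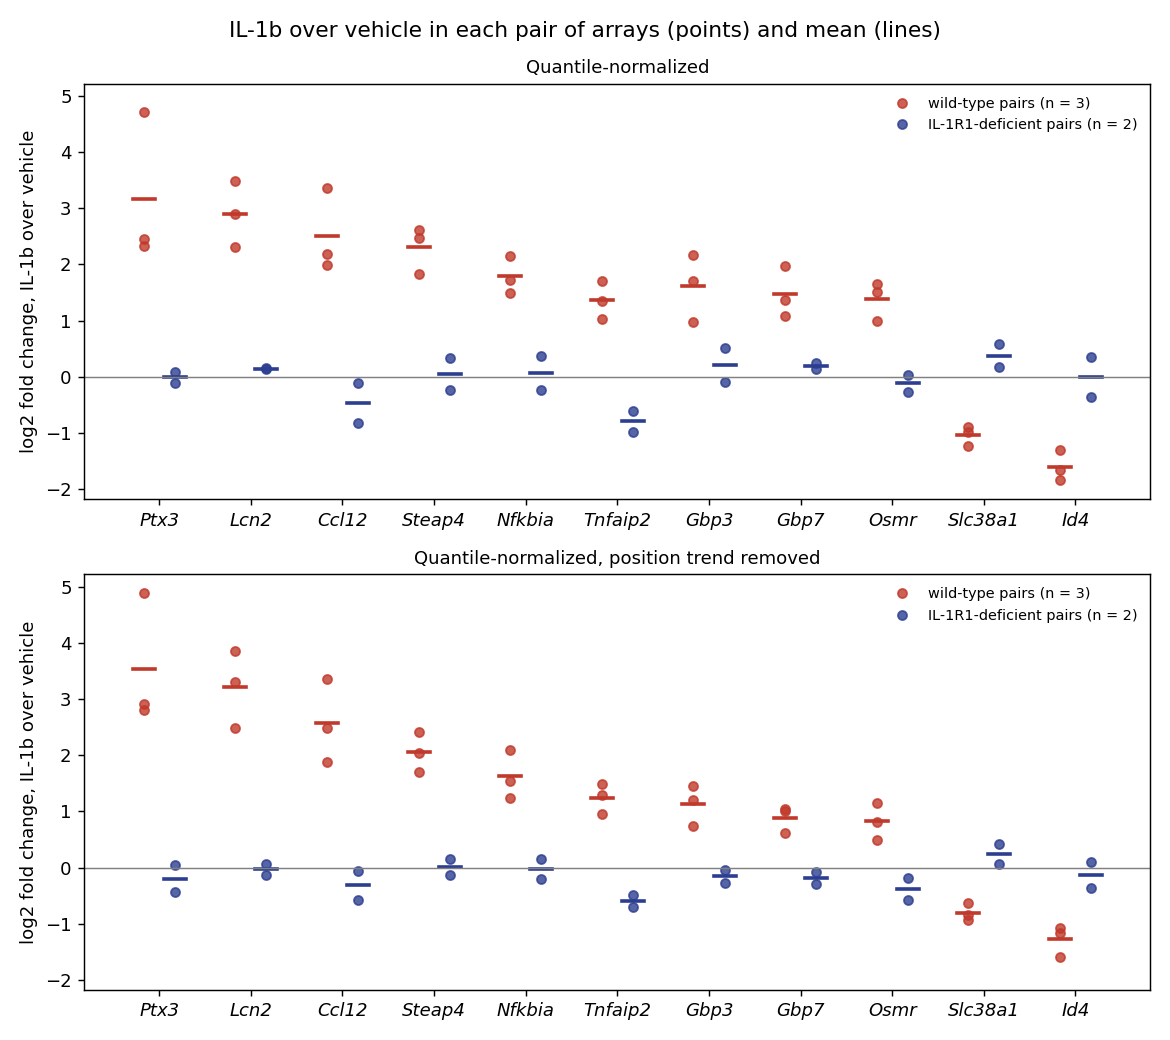
Points are the log2 fold change of IL-1β over vehicle in each pair of arrays (vertical axis) for 11 named genes (horizontal axis), 3 wild-type pairs in red and 2 IL-1R1-deficient pairs in blue, and lines are means. All wild-type points of Ptx3, Lcn2, Ccl12, Steap4 and Nfkbia lie above the IL-1R1-deficient points, before (top) and after (bottom) the position trend was removed. The naming rule for the difference between genotypes required such separation before trend removal, for Nfkbia at its second probe.

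In the chemokine list 4 of 9 measured members rose past the threshold in wild-type glia, and 5 passed when adjusted over the list alone. Beside Ccl12 these were Cxcl12 (log2 0.90; a second probe gave -0.36), Cx3cl1 (0.70) and Ccl4 (0.63), and camera gave an adjusted p = 0.00236 for the list (adjusted p = 0.408 with an estimated correlation). Only Ccl12 passed among the 9 after trend removal, when the list's adjusted p was 0.00392. In the NF-κB list 4 of 14 members rose (5 adjusted over the list alone): Nfkbia, Tnfaip2, the apoptosis inhibitor Birc3 (log2 0.95) and the kinase Tbk1 (0.72; a second probe gave -0.08, and with the trend removed they had 0.24 and 0.25). Its adjusted p was 0.00302 (adjusted p = 0.453 with an estimated correlation), and with the trend removed Nfkbia and Tnfaip2 passed (list adjusted p = 0.000293). In the acute phase and complement list 3 of 11 members rose, Lcn2, Steap4 and Ptx3, and 5 members passed adjusted over the list alone, 4 higher and 1 lower. The list's adjusted p was 0.00238 (adjusted p = 0.408 with an estimated correlation), and the same 3 genes passed with the trend removed (2.59e-05).

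Genes of oxidative phosphorylation shifted lower as a list (adjusted p = 0.0194, and adjusted p = 0.408 with an estimated correlation), although 0 of 13 members passed in limma, over all probes or over the list alone. The median log2 change was -0.31, 12 of 13 members were negative, and Ndufb9 and Sdhb had -0.51 and -0.54. After trend removal the median was -0.25 and the list's adjusted p was 9.05e-05. The list did not pass in 8 of 17 other settings, among them all 12 columns (adjusted p = 0.121) and no culture block (0.0833). In the astrocyte list 2 of 5 members fell, Id4 and the glutamine synthetase Glul (log2 -0.84; a second probe gave -0.10), and the same number passed adjusted over the list alone. The list's adjusted p was 0.0355 (adjusted p = 0.408 with an estimated correlation), and with the trend removed 1 member, Id4, passed (list adjusted p = 0.001), while Glul had -0.47.

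Markers of other cell types gave no list past the threshold in the quantile-normalized values. Of 12 microglia and macrophage markers 0 passed (median log2 -0.15, adjusted p = 0.204), and 0 of 5 oligodendrocyte, 0 of 6 neuron and 0 of 8 meningeal fibroblast markers did (adjusted p = 0.199, 0.509 and 0.365). Among 8 endothelial and mural markers Emcn rose (log2 0.84; 0.30 and not passing with the trend removed), and the list's adjusted p was 0.363. A further 3 lists passed with the trend removed: interferon response higher (0.00441), ribosomal proteins lower (0.00441) and endothelial and mural markers higher (0.0415). None of the 8 lists then past the threshold held (adjusted p = 0.253 with an estimated correlation for each).

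In limma 353 of 5713 probes passed in wild-type glia, 260 higher and 93 lower, from 278 named genes. Of the 353, 189 had a value on all 12 columns, and 149 of these passed there. With the position trend removed 23 passed, 17 higher and 6 lower, and 21 of them were among the 353. Across probes the fold change correlated with that of the next probe in the list order (r = 0.636), and with that of the probe 24 or 384 places on (r = 0.596 and 0.6), periods read as the columns and wells of plates; this layout was inferred from the values. After trend removal these were 0.091, 0.103 and 0.104; neighbouring probes are not independent. Of the 23 probes, 10 fell outside the rule for named genes and were chosen after their values were seen. Their log2 changes with the trend removed were 1.33 for Lrig1, 1.22 for Trmt1l, 0.94 for Gbp9, 0.78 for Smim3, -0.68 for Grk5, -0.70 for Purb, -0.76 for Hadhb and -0.71 for Cyb5r3, and 1.51 and 1.05 for the probes without a gene name, 4650 and 5279. In most other settings Purb, Cyb5r3, Grk5, Hadhb and Smim3 did not pass. The Trmt1l probe lies 2 places from probe 4650, and second probes gave -0.01 for Trmt1l and 0.12 for Purb.

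The wild-type count was 14 without the culture block, 28, 53 and 203 without wild-type replicate 1, 2 and 3, 175 with the wild-type arrays alone or without either IL-1R1-deficient pair, 69 without the copied arrays and their sources, and 150 (139 higher, 11 lower) on all 12 columns, as set before the copies were known. After trend removal it was 8 without the block, 12 and 11 without wild-type replicate 1 and 3, 15 without either IL-1R1-deficient pair and 13 on all 12 columns, and an ordinary unmoderated test called 1 probe before and 0 after trend removal.

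**Figure D3:**
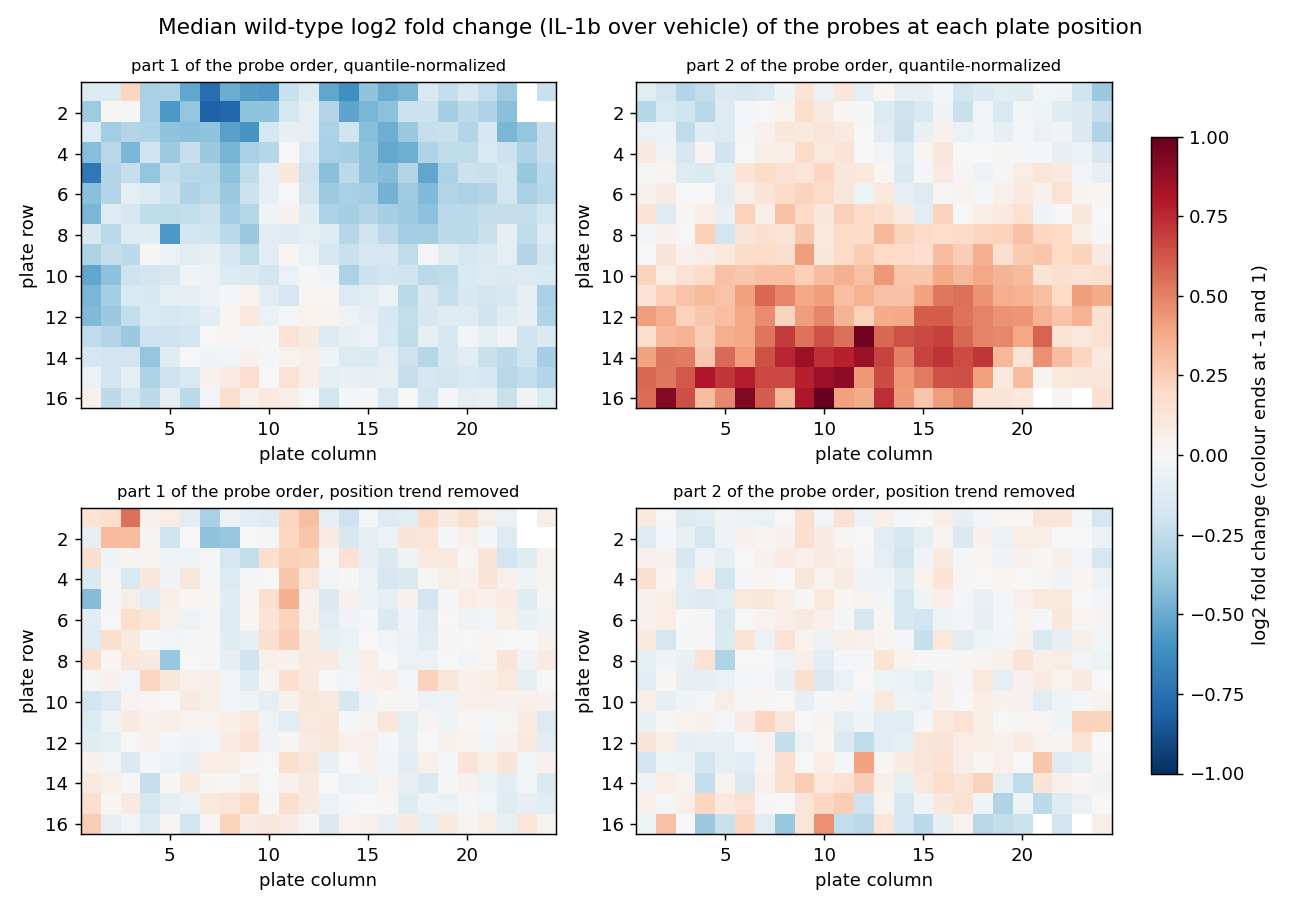
Each cell is the median wild-type log2 fold change (colour, IL-1β over vehicle) of the probes at 1 inferred plate row (vertical axis) and plate column (horizontal axis), in 2 parts of the probe order, before (top) and after (bottom) the position trend was removed. Well medians ran from -0.81 to 1.13 before and from -0.43 to 0.55 after.

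In IL-1R1-deficient glia, which show whether glia respond to IL-1β without this receptor, none of the genes that rose most in wild-type cells passed. Lcn2 had a log2 change of 0.15 ± 0.26 (SE, n = 2 pairs) and Nfkbia 0.07 ± 0.24, and both were -0.03 with the position trend removed. Ptx3 had 0.09 and -0.10 in the 2 pairs, and Steap4 0.34 and -0.23. Ccl12 had -0.82 and -0.11, and Tnfaip2 was lower in both pairs (-0.60 and -0.97). Second probes had 0.165 and -0.199 for Ccl12, and -0.415 and -0.251 for Nfkbia. Il1r1 had 0.10 ± 0.22 (0.18 with the trend removed).

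No probe passed in limma (0 of 5713), and 434 had an unadjusted p under 0.05, where chance gives 286. The genes with the smallest p did not pass (adjusted p = 0.601): Ado (log2 1.12 ± 0.26 SE), the zinc transporter Slc39a4 (1.05), Ptpra (0.90), Ctbp1 (0.89) and Tgfbr3 (0.71) were higher in 2 of 2 pairs, and Ifrg15 (-1.05), Ola1 (-1.04), Agxt2 (-0.99) and Tmcc1 (-0.87) lower. Agreement of the 2 pairs was required by the rule for naming these genes. Hoxc5 entered through a second probe (-1.02), and its brightest probe had -0.18. Other probes gave 0.48 for Agxt2, 0.08 and -0.02 for Ifrg15, -0.37 for Ola1, -0.38 for Tmcc1 and 0.12 for Tgfbr3. No list passed. In the ribosomal protein list Fau (-0.74), Rpl23 (-0.73) and Rpl21 (-0.55) passed adjusted over the list alone, and the list's adjusted p was 0.27. With the trend removed that list shifted lower (adjusted p = 0.0145, and adjusted p = 0.988 with an estimated correlation), with Fau at -0.87 and Rpl21 at -0.68.

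The count stayed at 0 with the trend removed (359 at an unadjusted p under 0.05) and on all 12 columns (242). It was 108 (40 higher, 68 lower) with the IL-1R1-deficient arrays fitted alone, 153 (1 higher, 152 lower) without normalization between arrays and 177 (1 higher, 176 lower) with median centring, or 146 (1 higher, 145 lower) for both scalings with the trend removed; of the 177 probes, 87 were in the brightest 10%. The main fit gives the genotypes 1 shared estimate of the spread, and the wild-type arrays alone gave 175 probes. Across probes the SD of the log2 fold changes was 0.356 and 0.33 in the IL-1R1-deficient pairs. In the wild-type pairs it was 0.409, 0.487 and 0.523.

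The response of 6 genes to IL-1β differed between the genotypes, the comparison that tests whether the response depends on genotype; the genotypes were separate cultures on separate arrays. The wild-type response exceeded that of IL-1R1-deficient glia by 8.98-fold for Ptx3 (log2 3.17 ± 0.54 SE, n = 3 and 2 pairs, or 2.39 without wild-type replicate 1), 7.87-fold for Ccl12 (log2 2.98 ± 0.39 SE), 6.71-fold for Lcn2 (log2 2.75 ± 0.33 SE), 4.75-fold for Steap4, 4.43-fold for Tnfaip2 and 3.29-fold for Nfkbia. Adjusted p ran from 0.00593 for Lcn2 to 0.0423 for Nfkbia, which did not pass in 13 of 21 other settings. Second probes of Ccl12 and Nfkbia passed too (log2 2.27 and 1.90), as did probe 4650, which has no gene name. All 9 probes passed with the position trend removed, Ptx3 at log2 3.72, Lcn2 at 3.24, Ccl12 at 2.89, Steap4 at 2.05, Tnfaip2 at 1.83 and Nfkbia at 1.65.

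Among genes with a lower response in wild-type cells, Id4 (log2 -1.60 ± 0.30 SE), Maged1 (-1.68), Scpep1 (-1.74) and Slc38a1 (-1.40) had adjusted p = 0.0642 and Kmt2e (-1.29) had 0.0878, so none passed. Other probes gave -0.36 for Maged1, and 0.41 and 0.31 for Kmt2e. The difference for Il1r1 was 0.48 ± 0.29 (SE, adjusted p = 0.478). In the acute phase and complement list 3 of 11 members differed, and in the NF-κB list 2 of 14, with the same numbers adjusted over each list alone. These lists passed with adjusted p = 0.0388 and 0.0491 (adjusted p = 0.55 with an estimated correlation for both), and with the trend removed with 0.00306 and 0.0175 (0.571). The chemokine list, in which Ccl12 differed and Ccl4 (0.79) also passed adjusted over the list alone, had an adjusted p = 0.0605.

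Limma called 9 of 5713 probes, with 804 at an unadjusted p under 0.05. All 9 had the larger response in wild-type glia, and 7 of them had a value on all 12 columns. Some other settings also called probes with the smaller response in wild-type glia, such as 16 of 30 with gaps kept. Without wild-type replicate 2 and 3 these were 8 of 30 and 4 of 13. The count was 0 without the culture block (362 at an unadjusted p under 0.05), 0 with an unmoderated test (591), 240 without normalization and 264 with median centring, 3 and 30 without wild-type replicate 1 and 2, and 3 and 2 without IL-1R1-deficient replicate 1 and 2. After trend removal it was 1 without the block, 14 without wild-type replicate 2 and 0 without either IL-1R1-deficient replicate (189 and 325 at an unadjusted p under 0.05), where 1 pair is left and is assumed to vary like the others; on all 12 columns 8 probes passed before trend removal, 7 of them shared.

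Vehicle-treated glia of the genotypes differed in 1 named transcript, the comparison that asks whether expression differs by genotype without IL-1β. 2610318N02Rik was 4.20-fold higher in IL-1R1-deficient glia (log2 2.07 ± 0.29 SE, n = 2 and 3, adjusted p = 0.0468). It no longer passed with the position trend removed (log2 1.71 ± 0.26 SE, adjusted p = 0.121), and its second probe gave 0.25. The retinol dehydrogenase Rdh5 (log2 1.91 ± 0.30 SE, adjusted p = 0.058), Exoc3 (1.43), Dedd2 (1.31) and Hao1 (1.28) were higher without passing, and second probes of Rdh5 and Dedd2 gave 0.09 and 0.01. Ecrg4 (-1.32), Tgfbr3 (-1.30), the growth factor Ptn (-1.28), the actin cross-linker Flna (-1.18) and Nol9 (-0.95) were lower without passing (adjusted p between 0.085 and 0.169), and other probes gave -0.39 for Tgfbr3 and -0.40 and -0.91 for Flna. The log2 difference was 0.10 ± 0.27 (SE) for Il1r1, 0.31 for Nfkbia and -0.43 for Lcn2.

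Oxidative phosphorylation was the only list of 23 that passed between the vehicle groups, lower in IL-1R1-deficient glia (adjusted p = 0.043, and adjusted p = 0.634 with an estimated correlation). Its median log2 difference was -0.39, 12 of 13 members were negative, and Sdhb had -0.98 and Ndufa2 -0.75, although 0 of 13 passed in limma, also adjusted over the list alone. After trend removal its adjusted p was 0.0041 (0.837 with an estimated correlation). It did not pass in 10 of 17 other settings, and the setting without a culture block repeats the main list test. Among the 10 were all 12 columns (adjusted p = 0.884) and the fit without wild-type replicate 1 (0.124). In each of these fits 1 other list passed, higher in IL-1R1-deficient glia. No list test of the genotype difference had a culture block, so the arrays of a culture counted as independent. No marker list of another cell type passed (the lowest adjusted p was 0.398, for meningeal fibroblast markers).

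In limma 1 probe passed and 489 had an unadjusted p under 0.05. With the trend removed 0 passed (442). On all 12 columns 0 passed (59), and the called probe was not among those tested there. The count was 0 without wild-type replicate 1 and without IL-1R1-deficient replicate 1 or 2, 7 without wild-type replicate 2, and 102 with median centring; without wild-type replicate 3 another probe passed, lower in IL-1R1-deficient glia. Without normalization the median of all probes was 1.80 higher (log2) in the IL-1R1-deficient arrays, and Lcn2, Tgfbr3, Ptn, Ecrg4, Flna and Nol9, whose differences were then positive, stayed below that shift. The IL-1R1-deficient vehicle arrays are shared with the IL-1β comparison of that genotype. There, with none passing, Tgfbr3 was higher (log2 0.71) and 2610318N02Rik (-1.01), Rdh5 (-0.72) and Exoc3 (-0.68) were lower, each against its genotype difference.

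Across the 5713 probes the mean log2 fold changes of the 2 genotypes were not correlated (Pearson r = 0.015, Spearman rho = -0.023). Of the 8 distinct patterns of exchanged IL-1β and vehicle labels within pairs, 8 gave an r as large in size (exact permutation p = 1, the smallest possible being 0.125), and genes are not independent replicates. With the trend removed r was 0.029 and rho 0.032 (7 of 8 patterns, exact permutation p = 0.875). On all 12 columns r was 0.372, where a copied column enters both genotypes.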

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

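Among the tests given here, those chosen only after the result was seen were the neighbours' share over all 353 probes, the count still passing after trend removal, the share of these changes found in IL-1R1-deficient glia, the share of probes at 1 ratio, and, for the correlation of the IL-1R1-deficient pairs, its value after removal of the position trend and the correlation between genotypes; the position correction was also chosen after seeing the data.

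The test of the difference between the IL-1β effects singled out 9 probes. The response was larger in wild-type glia by log2 2.98 and 2.27 for the probes of Ccl12, 2.75 for Lcn2, 1.72 and 1.90 for those of Nfkbia, 3.17 for Ptx3, 2.25 for Steap4, 2.15 for Tnfaip2 and 1.87 for probe 4650, which has no gene name. Each of the 9 rose in 3 of 3 wild-type pairs.

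Many wild-type changes followed the probe's place in the layout inferred from the probe order: over the 353 probes, uncalled neighbours in it carried a median share of 0.506 of the log2 change (quartiles 0.375 and 0.581), so a trend along this layout is a candidate explanation for part of them. Once it was removed 332 no longer passed, of which 330 shrank and 2 did not. The median log2 size of the 332 went from 0.77 to 0.30 (median SE of a probe 0.18 and 0.14), and what remains of them stays open. Their own share, 0.517, and that of the other 21, 0.086, decide nothing, because the removal itself sorts the probes this way. Any other split of the arrays gave at most 3 probes, before trend removal as well as after. This cannot tell a trend from a response, because exchanged labels break up either. These 21 still passed, at a median log2 size of 1.43 before and 1.24 after (median SE of a probe 0.19 and 0.15). They were picked for passing again, so their passing decides nothing for any single probe. Their number was not fixed and exceeded the 3 probes of any other split. That argues against the removed trend as the whole source of the 353 changes, while a trend that the smoothing left behind stays open. With the trend removed, the median log2 change of these 21 probes, signed by the wild-type direction, was 1.244 in wild-type and -0.093 in IL-1R1-deficient glia. The ratio of these medians was -0.075. A response that needs IL-1R1 predicts a low ratio. So does any change confined to the wild-type arrays, because the 21 were picked there. The ratio cannot tell these apart, and any other difference between the arrays or cultures of the genotypes stays open, as it was not tested.

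The 6 wild-type arrays can be divided in 10 ways into 3 and 3, too few for a share under 0.05. Of these splits 1, the real one, gave as many as its 353 probes, and the highest other gave 3; with the position trend removed the real split gave 23, the highest other 3, and again 1 split gave as many. Among the 4 splits that part every pair the highest other gave 0 in both fits, and the remaining splits part 1 pair and keep both arrays of each other culture on 1 side.

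The columns of IL-1R1-deficient replicate 3 repeat other columns. At least 99.2% of shared probes lay at 1 ratio, against at most 0.0857% in other pairs of columns, which argues against separate hybridisations that came out alike. By these copies the third pair would compare vehicle arrays of the genotypes, and its fold changes had an r of 0.061 and 0.154 with genotype differences from other arrays and of 0.116 with the IL-1β effect of IL-1R1-deficient replicate 2. These low values leave open which of the readings, a genotype difference or an IL-1β effect, the pair holds; they cannot be told apart here. Which column of each matching pair is the original was not tested.

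The fold changes of the 2 distinct IL-1R1-deficient pairs correlated across probes (r = 0.359), although no probe passed. The correlation was 0.263 after removal of the position trend and 0.244 after a brightness trend was removed as well, which argues against either trend as its whole source. Among the 3 wild-type pairs r was 0.441, 0.301 and 0.27, and 0.185, 0.239 and 0.177 with the position trend removed. Between the mean fold changes of the genotypes r was 0.029, but with labels exchanged within pairs r reached 0.256 in size, so an IL-1β response that does not need IL-1R1 and is shared with wild-type glia stays open. A response limited to IL-1R1-deficient cells and a handling difference between treated and control dishes also stay open, as neither was tested.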

How the results depend on the processing

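The fit on all 12 columns was set beforehand, and the fit on 10 arrays that takes its place was chosen after seeing the data. The settings without the copied columns and their sources, with the position trend or part medians removed, with normexp, with gaps kept, with median centring and a brightness trend removed, and all planned settings repeated after trend removal were chosen after seeing the data. Of 2062 values of single genes and lists under other settings, 1628 kept their direction and side of the threshold, 362 no longer passed, 52 newly passed and 20 turned sign, lists being counted by the direction of their test. Some settings repeat each other. For a wild-type effect these are wild-type arrays alone and either IL-1R1-deficient pair left out. With the trend removed they are the values as deposited and with median centring. For lists in the genotype difference, the setting with no replicate block repeats the main test. Such tallies therefore do not count separate checks. For Lcn2, Ptx3, Ccl12, Steap4, Nfkbia and Tnfaip2 in wild-type glia, 273 of 288 values passed; 14 of the other 15 came from the unmoderated test, and Nfkbia with the trend removed and no replicate block was the other. Their difference between genotypes was lost more often: in 13 of 21 settings for Nfkbia (11 of 19 with the trend removed), 7 of 21 for Ptx3, 5 of 21 for Steap4, 5 of 20 for Tnfaip2, 3 of 21 for Ccl12 and 3 of 20 for Lcn2. Other calls lost in most settings were, with the trend removed in wild-type glia, Slc38a1 (12 of 19), Osmr (14 of 20), Purb (15 of 19), Cyb5r3 (14 of 19), Grk5 (13 of 19), Hadhb (13 of 19) and Smim3 (11 of 18). The same held for 2610318N02Rik (14 of 20) and oxidative phosphorylation (10 of 17) in the genotype difference and for the NF-κB list (9 of 17) in the difference of the responses. Left-out settings: the planned removal of knockout replicate 3 is the fit reported, and for the difference no fit on 1 genotype exists. Where 1 pair or vehicle array is left in a genotype, it is assumed to vary like the others. A normexp background correction was among the settings, but how far background in the intensities limits the fold changes was not measured. Across other settings the wild-type log2 change ran from 0.8 to 3.3 for Mir17hg and from 0.5 to 2.9 for Rrad. Except where fewer probes or arrays were used, the cause of the changes below was not tested.

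For the 353 wild-type probes the count was 14 with no replicate block, 175 on wild-type arrays alone, 151 without the dimmest probes (2857 kept), 199 with an offset, 1 with the unmoderated test, 150 on all 12 deposited columns, 69 with copied arrays and their sources left out, 633 with gaps kept, 23 with the position trend removed and 37 with part medians removed; leaving out 1 replicate gave 28 to 203. After trend removal (23) it was 8 with no replicate block, 15 on wild-type arrays alone, 0 with the unmoderated test and 13 on all 12 columns; leaving out 1 replicate gave 11 to 21.

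For IL-1R1-deficient glia (0) the count was 108 on that genotype's arrays alone, 153 as deposited with no normalization and 177 with median centring, and after trend removal 146 under each of these scalings. Removing a brightness trend after median centring gave 0 (564 at an unadjusted p under 0.05).

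For the difference between genotypes (9) the count was 0 with no replicate block, 240 as deposited, 264 with median centring, 5 with an offset, 0 with the unmoderated test, 30 with gaps kept, 5 with part medians removed, 1 with normexp and 20 with median centring and brightness trend removed; leaving out 1 replicate gave 2 to 30. After trend removal (9) it was 1 with no replicate block, 18 as deposited, 18 with median centring, 14 with eBayes trend and robust and 0 with the unmoderated test; leaving out 1 replicate gave 0 to 14.

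For the genotype difference in vehicle glia (1) the count was 0 on vehicle arrays alone, 0 with a replicate block by number, 0 as deposited, 102 with median centring, 0 without the dimmest probes (4285 kept), 7 with an offset, 0 with eBayes trend and robust, 0 on all 12 columns, 0 with copied arrays and their sources left out, 0 with gaps kept, 0 with the position trend removed, 0 with part medians removed, 0 with normexp and 13 with median centring and brightness trend removed; leaving out 1 replicate gave 0 to 7. After trend removal (0) it was 19 as deposited and 19 with median centring, and leaving out 1 replicate gave 0 to 1. Limma fitted each of these, and the counts at an unadjusted p under 0.05 ran from 59 on all 12 columns to 1004 as deposited.

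Of the gene lists, 5 passed in wild-type glia; on all 12 columns 5 passed as well, all higher, and 3 of them were the same lists. The number was 0 with an estimated correlation, 14 with fry in mixed directions, 3 with no replicate block, 8 with the position trend removed and 0 when an estimated correlation was added. In IL-1R1-deficient glia (0) it was 1 as deposited, 1 with median centring, 1 with the position trend removed and 1 when all 12 columns were added to that. For the difference (2) it was 0 with an estimated correlation, 1 with fry in one direction, 12 with fry in mixed directions, 1 with the mean of all probes of a gene, 0 as deposited, 0 with median centring, 6 on all 12 columns, 1 with part medians removed, and, with the position trend removed, 0 with an estimated correlation and 5 on all 12 columns; leaving out 1 replicate gave 1 to 3. For the genotype difference (1) it was 0 with an estimated correlation, 0 with fry in one direction, 0 as deposited, 0 with median centring, 2 with part medians removed and 0 with the position trend removed and an estimated correlation; leaving out 1 replicate gave 0 to 2.

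The correlation between genotypes (0.015) was 0.372 on all 12 columns, where a copied column enters both genotypes. The Il1r1 genotype difference (0.10) was 1.91 as deposited, near the shift of all probes. Values that turned sign did not pass. In IL-1R1-deficient glia they were Nfkbia at -0.082 as deposited, -0.11 with median centring, -0.064 on all 12 columns, -0.23 with copied arrays and their sources left out and -0.031 with the position trend removed (-0.23 to 0.37 without 1 replicate), Lcn2 at -0.027 with the position trend removed, and Hoxc5 at -0.38 to 0.017 without 1 replicate. In the genotype difference as deposited they were Tgfbr3 at 0.93, Ptn at 0.71, Ecrg4 at 0.89, Flna at 0.95, Nol9 at 1.29 and Lcn2 at 1.26. The median of the oxidative phosphorylation list was then 1.68 as well (from -0.39), below the shift of all probes, and its test still pointed lower without passing. Lcn2 also had 0.20 with copied arrays and their sources left out (-0.88 to 0.11 without 1 replicate), Il1r1 -0.022 with the position trend removed and -0.044 with part medians removed (-0.003 to 0.19 without 1 replicate), and Nfkbia -0.008 with median centring and brightness trend removed.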

Other observations

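Several fixed lists did not pass in wild-type glia but held members that did. In the prostaglandin and nitric oxide list 2 of 8 members rose, the prostaglandin E synthase Ptges (log2 1.07) and the argininosuccinate lyase Asl (0.72), with a list adjusted p = 0.0626 (adjusted p = 0.408 with an estimated correlation). In the interferon response list 3 of 16 rose: Gbp3, the deubiquitinase-like Usp18 (0.89) and the GTPase Iigp1 (0.85), with a list adjusted p = 0.0664. The oxidative stress and metallothionein list held the thioredoxin reductase Txnrd1, which rose (1.05), and the metallothionein Mt1, which fell (-0.87), among 13 members (adjusted p = 0.649). The metalloprotease Adam8 (0.94) rose among 17 adhesion and matrix protease genes (0.918), of which 5 passed adjusted over the list alone, 3 higher and 2 lower, and the transcription factor Klf6 (0.87) among 11 immediate early genes (0.435). The mitotic kinesin Kif20a (0.81) and Cdk2 (0.85) rose among 18 cell cycle genes (0.808), and Birc3 among 15 apoptosis genes (0.236), of which 2, both higher, passed adjusted over the list alone. In the other lists of this paragraph the same numbers passed adjusted over the list alone. The median of the adhesion list was negative (-0.09) and so was that of the cell cycle list (-0.06), whose test pointed higher. Of these genes only Gbp3 passed with the position trend removed.

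Other lists had no member past the threshold over all probes in wild-type glia. These were 6 cytokines and growth factors (adjusted p = 0.268), 5 genes of the IL-1 receptor family and its signalling (0.22), 14 antigen presentation and proteasome genes (0.689), 10 heat shock and unfolded protein genes (0.592), 10 cholesterol and lipid synthesis genes (0.0664) and 6 ribosomal protein genes (0.575). Adjusted over the list alone 2 of the 5 IL-1 receptor family genes and 1 of the 6 cytokines and growth factors passed, all higher, and none with the position trend removed; the other 4 lists had 0 before trend removal. All 10 cholesterol and lipid synthesis genes had negative log2 changes (median -0.26), and 8 of 10 did with the position trend removed (median -0.12, adjusted p = 0.185). The glycolysis and hypoxia list and the ependymal and choroid list had 4 measured genes each, too few for the list test, and 0 members passed in limma.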
